A study of Homo sapiens with 35 samples.

How the data were processed

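Messenger RNA was sequenced from 35 tumours grown in host animals from 22Rv1 and C4-2B cells, which are human prostate cancer lines. Per the labels' protocols, RNA was extracted with a column kit, polyadenylated transcripts were selected on magnetic beads, and libraries were made with the xGen Broad-range RNA kit. Whether that preparation keeps the strand of a transcript is not given in the sources used here, so genes that overlap or run antisense to one another are treated as uncertain. The authors deposited 1 table per tumour with a value for each of 62714 identifiers. The deposited values are expected counts (estimated counts per gene, as RSEM gives), here in whole numbers, and they were not normalised. Per the submitters' processing notes the tools were FastQC 0.11.8, STAR 2.7.8a and RSEM 1.3.3 on GRCh38. The annotation release, the step that made the values whole, the fate of reads shared by several genes and any removal of reads from host cells are not given in the sources used here. Expected counts divide reads among genes that share sequence, so values of near-identical copies depend on that division. Reads of host cells that map to human genes would add to markers of stroma and vessels.

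The identifiers were Ensembl genes, of which 62639 were matched to a symbol and 58274 to coordinates in GENCODE 29 on GRCh38, used only for positions and names. A further 4 identifiers named reporter or tool genes (egfp, tdtomato, mcherry and cre). They held 0.0372% of all counts, at most 0.233% in 1 library, and were left out of library sizes and tests. Total counts per library ran from 6492986 to 14705437, with a median of 11001345. No library was a near-duplicate of another of its own group, since the lowest chi-square per degree of freedom between libraries of 1 group was 5.17. Libraries of different groups were not compared in this way.

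Groups and replicate numbers were taken from the sample titles, and the genotype label was used to decide which groups form the Control side. The titles mark 3 series per line, written Ci, Ai_ND and Ai. The abbreviations are not defined in the sources used here. Ai carries the genotype label ADA over expression, and Ci and Ai_ND both carry the label Control. The titles call the replicates biological. Counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F-test on a model with 1 mean per group, fitted to each line separately. Libraries were scaled by the trimmed mean of M values, and genes were kept by edgeR's own filter on expression, which left 16087 genes in 22Rv1 and 15712 in C4-2B. The contrast ADA over expression vs Control set the Ai mean against the 2 Control series, each weighted 0.5. The remaining contrasts were Ai against Ai_ND, Ai against Ci, and Ai_ND against Ci as the background between Control series. The difference between lines was tested as an interaction over all 35 libraries, on 17856 genes. Every test was two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called at an adjusted p under 0.05. Levels are counts per 1e6 on the scaled library sizes (CPM), given as mean ± SD, and fold changes are on the log2 scale with a standard error (SE). The SE was worked back from the test, as the absolute fold change over the square root of F. It is approximate, above all for genes with few counts in a group. The level of ADA was also compared by exact permutation of libraries, on the log2 of CPM plus 0.5. For ADA over expression vs Control this permutation weighted all Control libraries equally. Log2 CPM in the list tests had a prior count of 2.

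Before the data were examined, 35 gene lists with 895 genes, the contrasts, the tests, the named-gene rule and most of the alternatives were fixed. Lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, with camera at a correlation estimated for each list, and with fry, whose directional p asks whether the genes of a list move on balance 1 way. A list needed 5 tested members, which left out 6 lists in each line. Adjustment ran over the lists of a comparison. Beside calls over all genes, members of a list are also counted with p-values adjusted over the list alone. The rule for naming genes in ADA over expression vs Control took ADA, then the 10 largest rises and 10 largest falls among called genes with an average log2 CPM of 1 or more, a symbol, and the same sign against both Control series, then up to 4 members of each list with the smallest p, then up to 10 genes called alike in both lines. For Ai_ND against Ci and for the difference between lines it took the 5 largest rises and the 5 largest falls. Members of long lists are given as a selection, and not every gene that the rule takes is named. Genes named in Ai against Ai_ND and in Ai against Ci, and genes of 22Rv1 named beyond the rule, were chosen after their values were seen.

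The alternatives were DESeq2 1.42.0, its size-factor scaling within edgeR, no filter on low counts, a minimum change of 1 on the log2 scale, blocks for the replicate number and for the first number of the title code, a covariate made from host-cell markers, only the groups compared, the pooled Control series, and leaving out each library in turn. After the data were seen, 5 libraries were also left out together. They are the libraries labelled 22Rv1 Ci 5, Ai 3 and Ai 6, whose ADA level went against the label, and C4-2B Ci 4 and Ci 5, which had high shares of mitochondrial counts. Summaries and plots were made in Python 3.11.15 with matplotlib 3.10.9.

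The procedure was tested on simulated counts drawn from the real means, spreads and library sizes, with 200 genes changed by a known fold in the Ai group. For ADA over expression vs Control in 22Rv1, edgeR found 53% of genes changed 1.5-fold, 86.4% of those changed 2-fold and 100% of those changed 4-fold, with 9 false calls among 15886 genes. For Ai against Ai_ND the shares were 33.3%, 78.8% and 100%, with 8 false calls, and for Ai against Ci they were 42.4%, 81.8% and 98.5%, with 5. In C4-2B, with 15572 genes, ADA over expression vs Control gave 29.2%, 72.7% and 96.9% at the 1.5, 2 and 4-fold sizes, with 6 false calls. Ai against Ai_ND gave 24.6%, 63.6% and 93.8%, with 1, and Ai against Ci gave 21.5%, 63.6% and 95.4%, with 9. Ai_ND against Ci, where nothing was changed, gave 0 calls by edgeR in both lines. On the same simulated sets DESeq2 made 28 false calls for ADA over expression vs Control in 22Rv1 and 23 in C4-2B. In a separate simulation in which the 44 tested proliferation genes were doubled in Ai, that list was called by all 3 list tests in both lines. Of the other 28 lists, 0 were called, except 1 by fry in 22Rv1. In both simulations each gene was drawn independently of the others. They therefore cannot show how the list tests fare where the genes of a list are correlated, as with the estimated correlation. Differences between libraries that many genes share were not simulated either. With such differences the real libraries may give lower shares found and more false calls.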

Results

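The series asked which genes respond when adenosine deaminase (ADA) is switched on in established prostate tumours. ADA converts adenosine to inosine and deoxyadenosine to deoxyinosine. The tumours were xenografts of cells in which ADA can be induced by tetracycline. 22Rv1 is a line from a relapsed human prostate xenograft, and C4-2B is a bone-seeking line derived from LNCaP. RNA was sequenced from 17 tumours of 22Rv1 and 18 of C4-2B. For 22Rv1 there were 6 tumours titled Ci, 5 titled Ai_ND and 6 titled Ai, and for C4-2B there were 6 in each of the 3 series. Only Ai carried the genotype label ADA over expression.

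Total counts per 22Rv1 library were 10109868 to 12469069 in Ci, 9315272 to 13137286 in Ai_ND and 10554590 to 14705437 in Ai. In C4-2B they were 6492986 to 10668248 in Ci, 10679080 to 13067160 in Ai_ND and 8581347 to 11561750 in Ai. The libraries labelled C4-2B Ci 4 and Ci 5 were the shallowest, with 7476856 and 6492986 counts. Mitochondrially encoded genes took 46.1% and 39.4% of their counts, against 4.80% to 13.6% in the other C4-2B libraries and 3.43% to 5.62% in 22Rv1. The nuclear noncoding RNA MALAT1 took a further 10.8% and 10.3% of the counts of these libraries and was their most abundant gene.

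ADA (ENSG00000196839, chromosome 20, 44619522 to 44652233, minus strand, GRCh38) was read first in every library, as a check of the labels. In C4-2B it stood at 18.3 ± 3.92 CPM in Ci (SD, n = 6) and 20.2 ± 4.45 CPM in Ai_ND (SD, n = 6), and at 361 ± 223 CPM in Ai (SD, n = 6). All 6 C4-2B Ai libraries, at 150 to 684 CPM, lay above all 12 Control libraries. ADA over expression vs Control was 4.23 (SE 0.26) on the log2 scale, with an adjusted p of 1.96e-08 by edgeR's quasi-likelihood test. An exact two-sided permutation test gave p = 5.39e-05, the smallest it can give. In 22Rv1 the level was 16.4 ± 23.8 CPM in Ci (SD, n = 6), 9.46 ± 1.53 CPM in Ai_ND (SD, n = 5) and 48.6 ± 32.2 CPM in Ai (SD, n = 6). 3 libraries went against their label. The library labelled 22Rv1 Ci 5 had 64.9 CPM, where the other Ci libraries had 4.45 to 8.08 CPM. The libraries labelled 22Rv1 Ai 3 and Ai 6 had 10.5 and 9.27 CPM, where the other Ai libraries had 49.5 to 83.0 CPM. With all libraries kept as labelled, ADA over expression vs Control in 22Rv1 was 1.97 (SE 0.52), an exact permutation p of 0.00501, and an adjusted p of 0.302 over all genes. Without the library labelled Ci 5 the value was 2.62 with an adjusted p of 0.0137, so that 1 library decided the call. Every direction given for 22Rv1 rests on these labels.

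**Figure D1:**
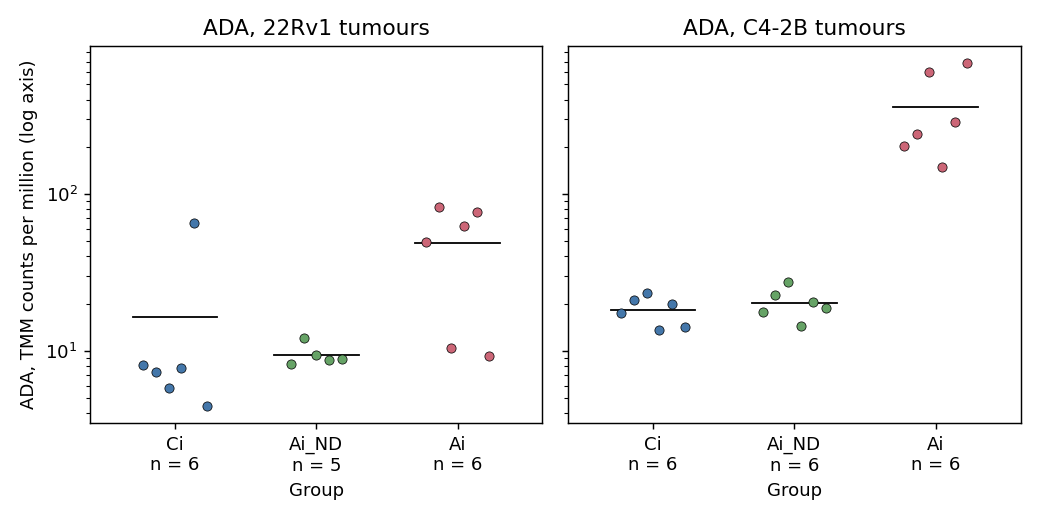
ADA level in CPM on a log axis for each of the 35 libraries, by cell line and series, with the group means. The 6 C4-2B Ai libraries lie at 150 to 684 CPM, above every Control library of that line, while the library labelled 22Rv1 Ci 5 (64.9 CPM) and those labelled 22Rv1 Ai 3 and Ai 6 (10.5 and 9.27 CPM) sit among the libraries of the other label.

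In 22Rv1, the comparison of ADA over expression vs Control called 0 genes, and the lists that passed by camera at its preset correlation were all lost with an estimated correlation. The 30 tested hypoxia genes had a median of 0.17 on the log2 scale (camera adjusted p 6.59e-07), the 20 glycolysis genes 0.08 (adjusted p 3.44e-04), and the 26 interferon response genes 0.13 (adjusted p 0.00961), each with adjusted p = 0.611 with an estimated correlation. The 44 proliferation genes had a median of -0.10 (camera adjusted p 4.26e-06, and adjusted p = 0.634 with an estimated correlation) and the 24 cholesterol synthesis genes -0.11 (camera adjusted p 0.00206, and adjusted p = 0.672 with an estimated correlation). Several of these medians average values of opposite sign against Ai_ND and against Ci, at -0.08 and 0.40 for hypoxia, 0.16 and -0.11 for interferon and -0.22 and 0.03 for proliferation genes. For each of these lists 0 members were called over all genes. With p-values adjusted over the list alone, 1 hypoxia and 1 interferon gene rose, and in the others 0 changed. MIR210HG, the host gene of a hypoxia-induced microRNA, stood at 39.3 ± 4.98 CPM in Ci (SD, n = 6), 40.2 ± 4.54 in Ai_ND (SD, n = 5) and 50.0 ± 6.38 in Ai (SD, n = 6), a difference of 0.33 (SE 0.09, adjusted p 0.343). The mitotic kinesin KIF23 differed by -0.23 (SE 0.08, adjusted p 0.529). Of the 28 adenosine and purine salvage genes 0 were called, and over the list alone 1 rose and 1 fell, around a median of -0.02 (camera adjusted p 0.697). The 41 androgen response genes had a median of -0.03 (adjusted p 0.219), with 0 called over all genes and 2 that fell over the list alone.

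The immediate early genes, which respond to handling of tissue as well as to growth signals, had a median of 0.13 over 27 genes (camera adjusted p 0.00206, and adjusted p = 0.611 with an estimated correlation). Of these 0 were called over all genes, and 4 rose when adjusted over the list alone. FOS, a transcription factor of this class, stood at 34.0 ± 7.28 CPM in Ci (SD, n = 6), 46.4 ± 6.53 in Ai_ND (SD, n = 5) and 58.0 ± 11.5 in Ai (SD, n = 6), a difference of 0.55 (SE 0.12, adjusted p 0.191, and 0.0303 by DESeq2). The 14 fibroblast and matrix genes had a median of 0.10 (camera adjusted p 0.00961, and adjusted p = 0.302 with an estimated correlation), with 0 called and 2 that rose over the list alone, among them COL6A2, a collagen VI chain, at 0.57 (SE 0.12, adjusted p 0.138 over all genes, and 0.00850 by DESeq2). The lipoprotein gene APOE had an adjusted p of 0.0668, the smallest value of the comparison, at 1.19 (SE 0.20). This averages 2.34 against Ai_ND with 0.04 (SE 0.22, adjusted p 0.989) against Ci. It was called without the library labelled Ai 2 (adjusted p 0.0478) and without Ai 5 (adjusted p 0.0366), and with all libraries by DESeq2 (adjusted p 3.07e-04), with a block for the title set (0.0237) and without a filter on low counts (0.00248).

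By edgeR's quasi-likelihood test 0 of 16087 genes were called, while 975 had an unadjusted p under 0.05 and DESeq2 called 34. Without the library labelled Ci 5, Ai_ND 2, Ai 2 or Ai 5 in turn the count was 2, and without the 3 libraries that went against their label it was 1, which is ADA itself, by whose level these libraries were chosen. By camera 10 lists passed, 6 higher and 4 lower. With an estimated correlation 0 did, and by fry 0. Without the 3 libraries the proliferation median was -0.04 (camera adjusted p 0.103), the interferon median 0.06 (0.153) and the hypoxia median 0.17 (2.43e-09, and adjusted p = 0.729 with an estimated correlation).

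In 22Rv1 Ai against Ai_ND, 96 genes rose and 23 fell, 46 of them by at least 1 on the log2 scale. APOE rose by 2.34 (SE 0.27, adjusted p 3.75e-04), from 2.24 ± 0.309 CPM in Ai_ND (SD, n = 5) to 11.4 ± 4.62 CPM in Ai (SD, n = 6). The interferon-inducible RNA sensor regulator DHX58 rose by 1.32 (SE 0.16, adjusted p 4.47e-04), the antigen-presenting molecule MR1 by 1.24 (SE 0.18, adjusted p 0.00302), the homeobox gene MEIS3 by 1.15 (SE 0.14, adjusted p 4.56e-04), and the sodium pump subunit ATP1B2 by 6.35 (SE 0.96, adjusted p 0.00302). The last was near its floor in Ai_ND, at 0.031 CPM. Among genes that fell were UGT2B15, an androgen-glucuronidating enzyme, by -1.39 (SE 0.23, adjusted p 0.00542), the cytochrome CYP4F8 by -1.05 (SE 0.20, adjusted p 0.0128), and the prostate stem cell antigen PSCA by -0.90 (SE 0.18, adjusted p 0.0211). UGT2B15 belongs to a family of close paralogs whose reads are divided between copies by the estimation of counts, so its value is uncertain.

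Matrix genes were the group that passed every list test in the upward direction in this comparison. Of the 14 fibroblast and matrix genes 2 rose and 0 fell, and 5 rose over the list alone, with a median of 0.33. COL6A2 rose by 1.24 (SE 0.14, adjusted p 3.75e-04) and the collagen COL1A1 by 1.01 (SE 0.17, adjusted p 0.00607). This list passed by camera (adjusted p 7.84e-05), with an estimated correlation (adjusted p = 0.0206) and by fry (adjusted p 5.45e-04). Of the 26 interferon genes 1 rose, BST2 (tetherin), by 1.96 (SE 0.33, adjusted p 0.00549), and 6 rose over the list alone, around a median of 0.16 (camera adjusted p 7.84e-05, and adjusted p = 0.105 with an estimated correlation). Of the 5 endothelium genes 1 rose, EGFL7, by 1.72 (SE 0.27, adjusted p 0.00344), and the list as a whole had a median of 0.00 (camera adjusted p 0.499). Of the 41 androgen response genes 3 fell, and 5 over the list alone, around -0.10 (camera adjusted p 4.96e-04, and adjusted p = 0.378 with an estimated correlation). The elongation factor ELL2 fell by -0.58 (SE 0.10, adjusted p 0.00680). The 44 proliferation genes had a median of -0.22 with 0 called (camera adjusted p 1.16e-14, and adjusted p = 0.378 with an estimated correlation).

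The count of 119 genes was unstable. It was 26, all higher, without the 3 libraries against their label, and 0 by edgeR with the mean of the host-cell lists as a covariate, to which the matrix and endothelium genes belong (2571 at an unadjusted p under 0.05, DESeq2 not run in that setting). With that covariate APOE was 2.18 (SE 0.35, adjusted p 0.0579), and over the 119 genes the median change went from 0.88 to 0.74 and the median SE from 0.16 to 0.22. Leaving out 1 library gave 187 (Ci 4), 73 (Ai_ND 1), 76 (Ai_ND 2), 56 (Ai_ND 3), 75 (Ai_ND 4), 79 (Ai 1), 58 (Ai 3) and 55 (Ai 6). PSCA lost its call without Ai_ND 1 (adjusted p 0.0663), Ai_ND 4 (0.0604), Ai 2 (0.0544), Ai 3 (0.0578) or Ai 6 (0.0713), and UGT2B15, CYP4F8, PSCA, COL1A1 and ELL2 lost theirs without the 3 libraries together. ADA was 2.36 (SE 0.68, adjusted p 0.120) and was called without Ci 5 (adjusted p 0.0167), which acts here only through the shared spread, and with all libraries by DESeq2 (0.0457), without a filter on low counts (0.0360) and with only the groups compared (0.0226).

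Ai_ND against Ci, both under the Control label, called 56 genes higher in Ai_ND and 227 lower in 22Rv1. APOE fell by -2.30 (SE 0.27, adjusted p 2.31e-04), from 11.1 ± 3.12 CPM in Ci (SD, n = 6). COL6A2 fell by -1.33 (SE 0.14, adjusted p 1.57e-04), DHX58 by -1.45 (SE 0.16, adjusted p 1.57e-04), BST2 by -2.10 (SE 0.33, adjusted p 0.00288), EGFL7 by -1.98 (SE 0.27, adjusted p 9.68e-04), MR1 by -0.89 (SE 0.18, adjusted p 0.0168), COL1A1 by -0.79 (SE 0.17, adjusted p 0.0255) and ATP1B2 by -5.07 (SE 1.05, adjusted p 0.0179). The intestinal protein PRAP1 fell by -2.11 (adjusted p 0.0270). Among genes that rose were PSCA at 1.35 (SE 0.19, adjusted p 9.68e-04), AGR2 at 1.46 (SE 0.33, adjusted p 0.0300), S100A14 at 1.42 (SE 0.30, adjusted p 0.0200), TMEM45B at 1.43 (adjusted p 0.0367) and GDF7 at 1.33 (adjusted p 0.0303).

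Of the 30 hypoxia genes 3 rose in Ai_ND against Ci, and 18 over the list alone, around a median of 0.41 (camera adjusted p 2.75e-15, and adjusted p = 0.161 with an estimated correlation). LOX, which crosslinks collagen, rose by 0.85 (SE 0.19, adjusted p 0.0303). Of the 41 androgen response genes 3 rose and 6 over the list alone (median 0.20, camera adjusted p 1.96e-06, adjusted p = 0.116 with an estimated correlation), ELL2 among them at 0.50 (SE 0.10, adjusted p 0.0151). Of the 26 interferon genes 3 fell and 8 over the list alone (median -0.28, camera adjusted p 1.54e-04, adjusted p = 0.116 with an estimated correlation). Of the 14 fibroblast and matrix genes 3 fell and 5 over the list alone, around -0.39. That list passed by camera (adjusted p 5.28e-05) and with an estimated correlation (adjusted p = 0.0192). Its mean level was 3.45 ± 0.108 log2 CPM in Ci (SD, n = 6), 3.05 ± 0.081 in Ai_ND (SD, n = 5) and 3.40 ± 0.140 in Ai (SD, n = 6). Of the 5 endothelium genes 1 fell (median -0.22, camera adjusted p 0.0326, adjusted p = 0.161 with an estimated correlation).

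With the host-list covariate edgeR called 0 genes here (3412 at an unadjusted p under 0.05, DESeq2 not run in that setting), while the median change over the 283 genes went from 0.79 to 0.64 and the median SE from 0.16 to 0.27. APOE was then -2.08 (SE 0.42) and COL6A2 -1.02 (SE 0.23). With only the groups compared the count was 78, under the 329 of Ai against Ai_ND in that setting. The count was 434 without the 3 libraries against their label, and 2569 genes had an unadjusted p under 0.05. Leaving out 1 library gave 176 (Ci 1), 110 (Ci 2), 563 (Ci 3), 182 (Ci 4), 547 (Ci 5), 155 (Ci 6), 123 (Ai_ND 1), 173 (Ai_ND 2), 132 (Ai_ND 3), 137 (Ai_ND 4) and 170 (Ai_ND 5). APOE, COL6A2, DHX58, BST2, EGFL7, PSCA and ATP1B2 were called in all 17 of these fits, with adjusted p of at most 0.0489. MR1 lost its call without Ai_ND 4 (adjusted p 0.0508) and ELL2 without Ai_ND 3 (0.0555). S100A14 lost it in 3 fits (up to 0.0730), COL1A1 in 3 (up to 0.0759), AGR2 in 5 (up to 0.105), LOX in 6 (up to 0.0908), PRAP1 in 6 (up to 0.0781), GDF7 in 6 (up to 0.102) and TMEM45B in 8 (up to 0.102). With only the groups compared AGR2, TMEM45B, S100A14, GDF7, PRAP1, MR1, ELL2 and LOX lost their calls as well (adjusted p 0.0504 to 0.122).

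Ai against Ci in 22Rv1 called 0 genes by edgeR's quasi-likelihood test, where 856 had an unadjusted p under 0.05 and DESeq2 called 1, FOS (adjusted p 0.0145). The 30 hypoxia genes had a median of 0.40, with 0 called over all genes and 16 that rose over the list alone (camera adjusted p 8.15e-27, and adjusted p = 0.206 with an estimated correlation). MIR210HG was at 0.35 (SE 0.10, adjusted p 0.926). The 27 immediate early genes had a median of 0.25, with 3 that rose over the list alone (camera adjusted p 1.07e-07, and adjusted p = 0.324 with an estimated correlation). FOS was at 0.77 (SE 0.14, adjusted p 0.488) and was called without the library labelled Ci 1 (0.90, adjusted p 0.0335), the only library whose removal moved this count, to 1. Without the 3 libraries against their label the count was 1, ADA, by whose level they were chosen.

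The calls against Ai_ND overlapped in 22Rv1. Of the 96 genes higher in Ai than in Ai_ND, 76 were also among the 227 higher in Ci than in Ai_ND, and of the 23 lower in Ai, 14 were among the 56 lower in Ci. Independent lists would share 1.35 and 0.08. Fold changes of the comparisons correlated across genes at r = 0.716 (genes are not independent replicates), where unchanged groups simulated against the same Ai_ND libraries gave r = 0.550 and 0 shared calls. The covariance was 0.0694, against 0.0290 simulated. With the Ai_ND libraries split between the comparisons, r was 0.256, the covariance 0.0443 and the shared calls 0, which was fixed in advance, as Ai then gave 0 calls.

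**Figure D2:**
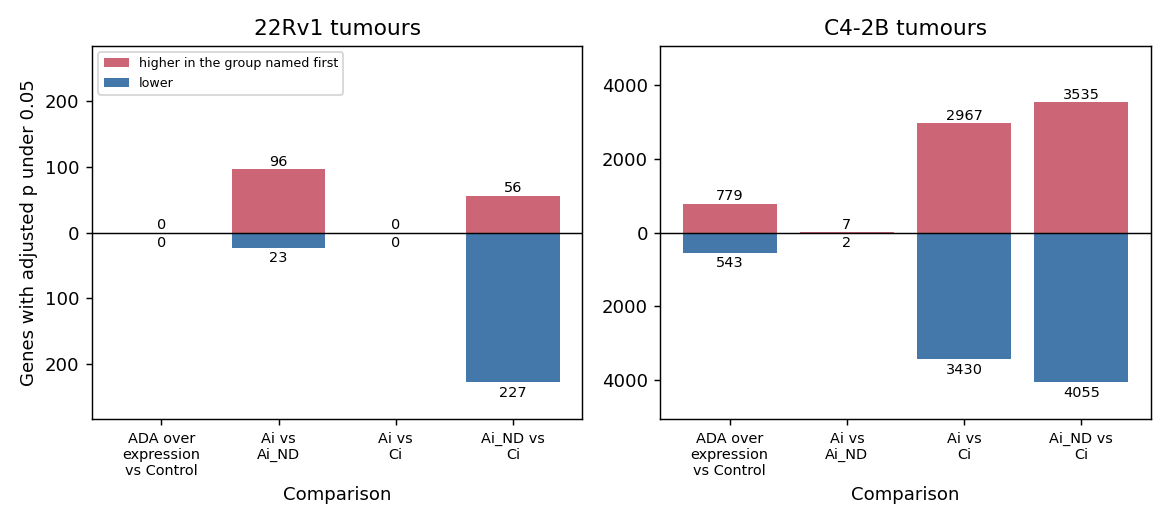
Genes called higher and lower at an adjusted p under 0.05 in each comparison of each line, by edgeR's quasi-likelihood test, as bars from 0. In C4-2B the comparisons against Ci call 6397 and 7590 genes and Ai against Ai_ND calls 9, and in 22Rv1 the counts run from 0 to 283.

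In C4-2B, ADA over expression vs Control called 779 genes higher and 543 lower. Of the 44 proliferation genes 36 rose and 0 fell, and 40 rose over the list alone, around a median of 1.02. The kinetochore gene NDC80 rose by 1.62 (SE 0.11, adjusted p 3.61e-08), the mitotic kinesin KIF20A by 1.51 (SE 0.11, adjusted p 1.46e-07), the spindle protein NUSAP1 by 1.47 (SE 0.13, adjusted p 9.28e-07) and the kinesin KIF11 by 0.99 (SE 0.09, adjusted p 1.82e-06). These values average over Control series that lay far apart. NDC80 stood at 3.95 ± 0.914 CPM in Ci (SD, n = 6), 39.7 ± 1.80 in Ai_ND (SD, n = 6) and 38.3 ± 4.87 in Ai (SD, n = 6), and KIF20A at 5.18, 45.5 and 42.9 CPM. Of the 1322 genes called, 1261 were called in the same direction in Ai_ND against Ci, and 6 in the same direction in Ai against Ai_ND. The proliferation list passed by camera (adjusted p 9.25e-42) and with an estimated correlation (adjusted p = 0.00402). Without the libraries labelled Ci 4 and Ci 5, in which mitochondrial genes took 46.1% and 39.4% of counts, 41 of its genes rose and the adjusted p with an estimated correlation was 0.0577.

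Of the 18 pyrimidine and deoxynucleotide genes 5 rose and 8 over the list alone (median 0.24), with thymidine kinase TK1 at 1.58 (SE 0.13, adjusted p 7.24e-07), the ribonucleotide reductase subunit RRM2 at 1.70 (SE 0.19, adjusted p 1.04e-05) and thymidylate synthase TYMS at 1.68 (SE 0.21, adjusted p 3.29e-05). The list had a camera adjusted p of 2.18e-05, and adjusted p = 0.309 with an estimated correlation, and its median against Ai_ND alone was -0.20. Of the 42 androgen response genes 8 rose and 1 fell, and over the list alone 18 rose and 1 fell (median 0.34, and -0.04 against Ai_ND alone, camera adjusted p 8.37e-09, adjusted p = 0.451 with an estimated correlation). Prostatic acid phosphatase ACP3 rose by 1.90 (SE 0.18, adjusted p 2.22e-06), the cation channel TRPM8 by 1.36 (SE 0.17, adjusted p 3.23e-05), GNMT by 0.94 (SE 0.14, adjusted p 2.19e-04) and the transporter SLC45A3 by 0.76 (SE 0.12, adjusted p 3.28e-04). Without the libraries labelled Ci 4 and Ci 5, 19 androgen response genes rose and 1 fell.

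Of the 28 adenosine and purine salvage genes 6 rose and 1 fell, and over the list alone 6 rose and 2 fell, around a median of 0.06 (camera adjusted p 0.131, fry adjusted p 0.0350). This list, which holds ADA itself, did not pass with an estimated correlation, where 1 list did, proliferation. Besides ADA, the surface peptidase DPP4, which binds ADA, rose by 1.26 (SE 0.18, adjusted p 1.83e-04), from 14.8 CPM in Ci to 112 in Ai_ND and 98.7 in Ai. Purine nucleoside phosphorylase PNP, the enzyme after ADA in this pathway, rose by 0.74 (SE 0.18, adjusted p 0.0147), from 12.1 CPM in Ci to 49.6 in Ai_ND and 41.3 in Ai, and lost the call without the library labelled Ai 1 (adjusted p 0.0626). The nucleotidase NT5C3A rose by 0.39 (SE 0.09, adjusted p 0.00955). Of 34 MYC and ribosome biogenesis genes 6 rose and 0 fell, SRM among them at 0.63 (SE 0.14, adjusted p 0.00547), and of 55 ribosomal protein genes 3 rose and 0 fell, RPL3 among them at 0.46 (SE 0.11, adjusted p 0.00980), a call lost without a filter on low counts (0.48, adjusted p 0.0826). Over the lists alone 12 and 20 rose, and against Ai_ND alone the medians were -0.10 and 0.08. Their camera adjusted p values were 7.99e-06 and 1.99e-11, and with an estimated correlation adjusted p = 0.198 and 0.619. Of 18 de novo purine synthesis genes 4 rose and 0 fell, and 6 over the list alone (median against Ai_ND alone -0.17), with SHMT1 at 0.45 (SE 0.09, adjusted p 0.00254; list camera adjusted p 0.00606, adjusted p = 0.633 with an estimated correlation). Of 26 epithelial junction genes 2 rose and 0 fell, TJP1 at 0.50 (SE 0.09, adjusted p 0.00123) and CLDN3 at 0.76 (SE 0.17, adjusted p 0.00648), and over the list alone 2 rose and 1 fell (median against Ai_ND alone -0.04, camera adjusted p 0.00507, adjusted p = 0.542 with an estimated correlation).

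The interferon response was the 1 list of 29 that passed in the downward direction. Of its 33 genes 0 rose and 6 fell, and 7 fell over the list alone, around a median of -0.42 (camera adjusted p 0.00933, and adjusted p = 0.633 with an estimated correlation). Against Ai_ND alone the median was 0.05, and against Ci alone -0.95. The transcription factor IRF1 fell by -0.87 (SE 0.19, adjusted p 0.00607) and IRF9 by -0.69 (SE 0.16, adjusted p 0.0121). Without the libraries labelled Ci 4 and Ci 5, 12 interferon genes fell. Of the 10 fibroblast and matrix genes 2 fell (median -0.07, camera adjusted p 0.298), and 4 over the list alone. The 13 mitochondrially encoded genes had a median of -0.73 with 0 called (camera adjusted p 0.298), and 0.27 without the libraries labelled Ci 4 and Ci 5 (adjusted p 0.169).

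Among genes named for the size of their change, the meiotic recombination gene MND1 rose by 2.02 (SE 0.20, adjusted p 3.12e-06), the synaptonemal complex genes SYCE2 by 2.00 (SE 0.24, adjusted p 2.21e-05) and SYCP2 by 2.49 (SE 0.42, adjusted p 7.26e-04), the ciliary gene TTC29 by 2.06 (SE 0.26, adjusted p 4.01e-05), and the membrane-trafficking genes CPNE4 by 1.99 (SE 0.23, adjusted p 1.96e-05) and SYT4 by 1.93 (SE 0.22, adjusted p 1.27e-05). Oestrogen receptor beta, ESR2, rose by 2.78 (SE 0.32, adjusted p 1.71e-05). Of the genes named here for their size, only ESR2 was also called in Ai against Ai_ND. With both Control series pooled, edgeR gave MND1 at 0.96 (adjusted p 0.552), SYT4 at 0.98 (0.562) and SYCP2 at 2.42 (0.0612). SYCP2 stood at 1.73 CPM in Ci and 1.95 in Ai_ND, and at 9.42 ± 8.03 CPM in Ai (SD, n = 6), and SYT4 at 22.0, 286 and 304 CPM in Ci, Ai_ND and Ai. The readthrough POC1B-GALNT4, at 3.24 (SE 0.73, adjusted p 0.00846), and the pseudogene ADAM1A, at 3.01 (SE 0.67, adjusted p 0.00708), share sequence with other genes and are uncertain. The largest falls were LINC02568 at -3.36 (SE 0.71, adjusted p 0.00523), the cancer-testis antigen SAGE1 at -2.58 (SE 0.52, adjusted p 0.00363), the lipocalin LCN10 at -2.54 (SE 0.45, adjusted p 0.00115) and FNDC5, precursor of irisin, at -1.86 (SE 0.25, adjusted p 8.25e-05). FBXL2, the NAD synthesis enzyme QPRT, the autophagy receptor OPTN, the endothelial receptor PROCR and the lipoprotein receptor LRP1 fell by -1.71, -1.61, -1.51, -1.45 and -1.45, with adjusted p of at most 0.00462. LRP1 stood at 57.5 CPM in Ci, 8.31 in Ai_ND and 8.02 in Ai.

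All of these genes other than PNP were called whichever library was left out. The count of 1322 (3691 at an unadjusted p under 0.05, 1969 by DESeq2) was 2402 without the libraries labelled Ci 4 and Ci 5, and 836 without the library labelled Ai 1. With both Control series pooled as 1 group of libraries it was 3, with ADA and ESR2 among them. The distance between the series then counts as spread, and the estimates change as well. Some shrank, as NDC80 at 0.80, and some grew in size, as LRP1 at -2.03.

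**Figure D3:**
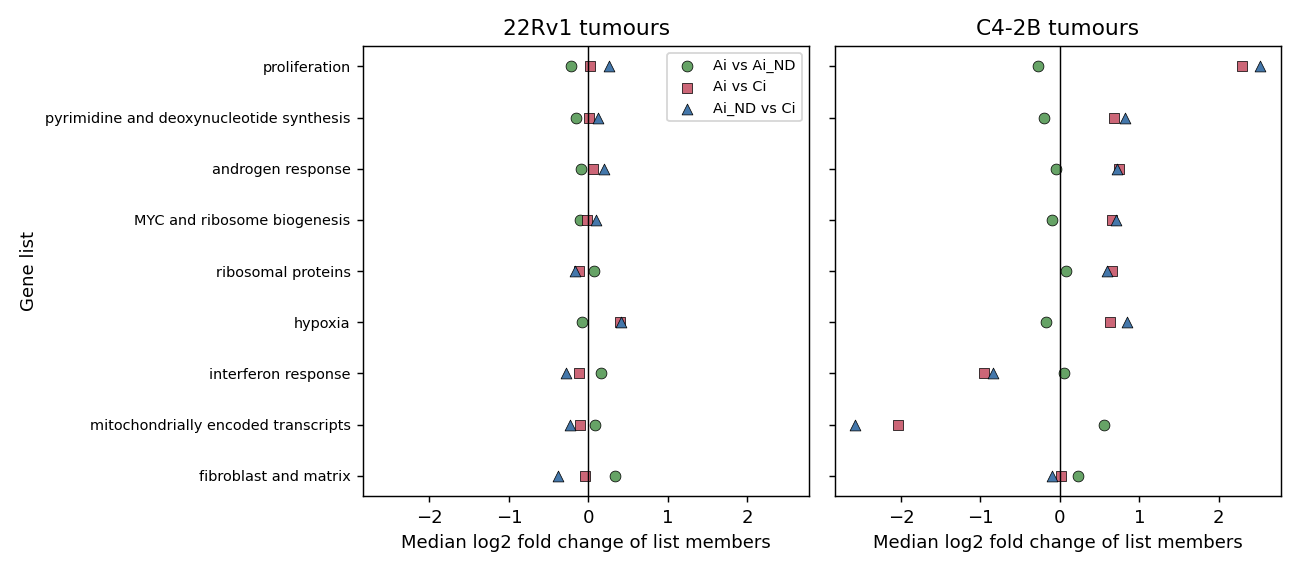
Median log2 fold change of gene lists in each comparison, by cell line, with 0 marked. In C4-2B the proliferation list stands at 2.29 for Ai and 2.52 for Ai_ND against Ci and at -0.27 for Ai against Ai_ND.

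Ai against Ai_ND in C4-2B, which differ in the genotype label and not in cell line, called 7 genes higher and 2 lower. ADA rose by 4.16 (SE 0.34, adjusted p 1.94e-06). NUDT9, an ADP-ribose pyrophosphatase, rose by 1.49 (SE 0.12, adjusted p 1.94e-06), from 46.2 ± 2.25 CPM in Ai_ND (SD, n = 6) to 130 ± 16.6 in Ai (SD, n = 6), and stood at 123 ± 23.2 CPM in Ci (SD, n = 6). Its neighbour on chromosome 4, the steroid dehydrogenase HSD17B11 (87336610 to 87391386, NUDT9 at 87422582 to 87459454), rose by 1.64 (SE 0.22, adjusted p 0.00154), from 6.52 ± 1.32 to 20.3 ± 2.01 CPM, with 16.1 ± 6.18 CPM in Ci (SD, n = 6 each). The unnamed gene ENSG00000286598 rose by 3.35 (SE 0.30, adjusted p 4.13e-06), from 0.416 to 4.35 CPM, with 14.6 CPM in Ci. RUFY3, an endosomal adaptor, rose by 1.06 (SE 0.18, adjusted p 0.0203), from 14.9 to 31.0 CPM, with 49.0 CPM in Ci. COLCA1 fell by -1.27 (SE 0.17, adjusted p 0.00154), from 60.2 to 24.9 CPM, with 3.76 CPM in Ci. GASK1B fell by -1.06 (SE 0.19, adjusted p 0.0342), from 18.2 to 8.72 CPM, with 1.85 CPM in Ci. COLCA1 lies antisense to other genes and is uncertain.

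In the remaining genes Ai was apart from both Control series. SYNE2, which links the nucleus to the cytoskeleton, rose by 1.54 (SE 0.25, adjusted p 0.0203) against Ai_ND and by 1.90 (SE 0.26, adjusted p 1.36e-05) against Ci, with 81.2 CPM in Ci, 104 in Ai_ND and 302 ± 156 in Ai (SD, n = 6). ESR2 rose by 2.03 (SE 0.37, adjusted p 0.0484) and 3.54, with 0.631, 1.68 and 6.87 ± 3.92 CPM. SYNE2 (chromosome 14, 63852983 to 64226433) and ESR2 (64084232 to 64338112) overlap, so reads of one can be counted for the other. Of the 44 proliferation genes 0 were called, around a median of -0.27 (camera adjusted p 9.01e-13, and adjusted p = 0.401 with an estimated correlation). The 18 pyrimidine genes had a median of -0.20 and the 20 glycolysis genes -0.23, with 0 called in either (camera adjusted p 7.29e-04 for both, adjusted p = 0.691 for both with an estimated correlation). The 13 mitochondrially encoded genes had a median of 0.55 with 0 called (camera adjusted p 0.00861, adjusted p = 0.691 with an estimated correlation).

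At an unadjusted p under 0.05 there were 683 genes, and DESeq2 called 19. ADA, NUDT9, HSD17B11, ENSG00000286598 and COLCA1 were called whichever library was left out. The count fell to 5 without Ai_ND 4, Ai_ND 5, Ai_ND 6, Ai 2 or Ai 4, and was 10 without the libraries labelled Ci 4 and Ci 5. SYNE2 and RUFY3 each lost their call in 7 of 18 such fits (adjusted p up to 0.0871 and 0.0854), GASK1B in 12 (up to 0.168) and ESR2 in 15 (up to 0.222). The call of ESR2 was also lost with DESeq2's size factors (adjusted p 0.0519), with a block for the title set (0.0756), with the host-list covariate (1.74, SE 0.37, adjusted p 0.255) and with only the groups compared (0.0814). SYNE2 lost its call in the last of these settings (0.0708) and with the covariate (1.37, SE 0.27, adjusted p 0.136), and RUFY3 with the covariate (1.03, SE 0.19, adjusted p 0.103).

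**Figure D4:**
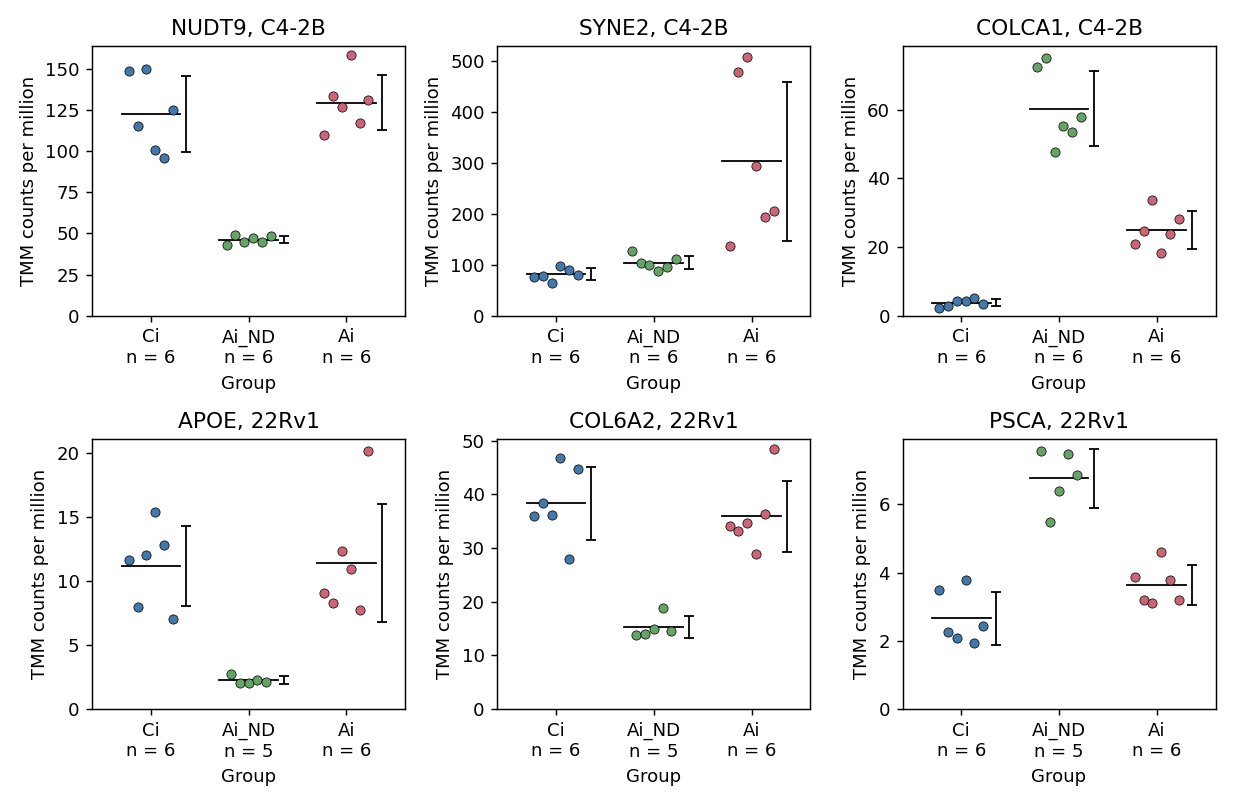
Level in CPM of selected genes in each library of the 3 series, with the group means. In C4-2B NUDT9 stands at 123 CPM in Ci, 46.2 in Ai_ND and 130 in Ai.

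The Ci series of C4-2B differed from both other series in a large share of the 15712 genes tested. Ai_ND against Ci called 3535 genes higher and 4055 lower, and Ai against Ci 2967 higher and 3430 lower. The neural transcription factor ATOH1 had 0 counts in all 6 Ci libraries and 6.39 ± 3.04 CPM in Ai_ND (SD, n = 6), at least 114-fold higher against a floor of 3 counts over the Ci group. The adrenergic receptor ADRA2A rose in Ai_ND by 4.65 (SE 0.42, adjusted p 7.26e-08), the progesterone receptor PGR by 5.33 (SE 0.83, adjusted p 4.28e-05) and LINC02326 by 4.70 (SE 0.62, adjusted p 7.69e-06). AGPAT4, an enzyme of phospholipid synthesis, fell by -5.66 (SE 0.43, adjusted p 6.31e-09), LINC02568 by -6.62 (SE 0.58, adjusted p 4.24e-08) and ATP1B2 by -8.54 (SE 1.18, adjusted p 1.13e-05). The level of ATP1B2 was 13.9 ± 24.6 CPM in Ci (SD, n = 6), most of it from the library labelled Ci 6 (63.9 CPM). NUDT9 fell by -1.41 (SE 0.12, adjusted p 4.56e-08), HSD17B11 by -1.34 (SE 0.22, adjusted p 7.54e-05) and RUFY3 by -1.71, while COLCA1 rose by 4.06 (SE 0.20, adjusted p 4.67e-11) and GASK1B by 3.21 (SE 0.22, adjusted p 1.47e-09).

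Of the 44 proliferation genes 42 rose and 0 fell in Ai_ND against Ci, and the same numbers in Ai against Ci, with medians of 2.52 and 2.29. MKI67, the Ki-67 antigen, rose by 2.15 (SE 0.24, adjusted p 8.00e-07) in Ai_ND, from 21.9 ± 9.44 CPM in Ci (SD, n = 6) to 95.7 ± 16.0 (SD, n = 6), and topoisomerase TOP2A by 1.68 (SE 0.47, adjusted p 0.00680). Over the list alone 44 rose in Ai_ND and 42 in Ai. The camera adjusted p was 3.20e-34 for Ai_ND and 5.03e-36 for Ai, and with an estimated correlation adjusted p = 0.0104 and 0.00820. In the androgen response list of 42 genes, 25 rose and 2 fell in Ai_ND (25 and 2 over the list alone) and 26 rose and 2 fell in Ai (29 and 3 over the list alone). Their camera adjusted p values were 3.13e-06 and 9.24e-08, with adjusted p = 0.482 and 0.484 with an estimated correlation. Of the 33 interferon genes 2 rose and 19 fell in each comparison, over all genes and over the list alone (camera adjusted p 7.22e-04 and 0.00167, adjusted p = 0.482 and 0.484 with an estimated correlation). All 13 mitochondrially encoded genes fell in each, with medians of -2.58 and -2.03 (camera adjusted p 0.00349 and 0.0290, adjusted p = 0.486 and 0.630 with an estimated correlation).

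Beside these groups stand the libraries labelled Ci 4 and Ci 5, with mitochondrial shares of 46.1% and 39.4% and MALAT1 shares of 10.8% and 10.3%. Without them 44 of 44 proliferation genes rose in both comparisons, with medians of 2.77 and 2.51 and adjusted p = 0.0904 and 0.0800 with an estimated correlation. Of the androgen response genes 26 and 25 rose, of 34 interferon genes tested 23 and 21 fell, and of the mitochondrial genes 4 and 0 fell. The counts of all genes were then 7320 and 6523, and with the host-list covariate the first was 3655, a setting in which TOP2A, at 1.54 (SE 0.72, adjusted p 0.126), lost its call with about the same change and a wider error, and ATP1B2, at -4.48 (SE 1.83, adjusted p 0.0825), lost it with a smaller change. The 10 tested genes of chromosome Y all fell in Ai_ND against Ci, with a median of -3.26, where the 16 tested in 22Rv1 had a median of 0.00.

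The comparisons of C4-2B against Ci shared most of their calls, 2701 higher and 3153 lower, where independent lists would share 668 and 885. Fold changes correlated across genes at r = 0.958 with a covariance of 0.776, and unchanged groups simulated against the same Ci libraries gave r = 0.527, a covariance of 0.0417 and 0 shared calls. With the Ci libraries split between the comparisons the shared calls were 1981 and 1679, where independent lists would share 853 and 819, with r = 0.527 and a covariance of 0.531. The split set Ai against Ci 1, Ci 2 and Ci 3, and Ai_ND against Ci 4, Ci 5 and Ci 6. The libraries labelled Ci 4 and Ci 5, with mitochondrial shares of 46.1% and 39.4%, thus fell on the same side, so these values also carry that imbalance.

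Between lines, the effect of ADA over expression vs Control differed for 949 of 17856 genes (3200 at an unadjusted p under 0.05), more positive in C4-2B for 535 and in 22Rv1 for 414. The difference in ADA itself was 2.28 (SE 0.63, adjusted p 0.0235), and its call was lost without the library labelled C4-2B Ai 6 (adjusted p 0.0561) and without the 5 doubted libraries (1.11, adjusted p 0.0681), of which 3 were chosen by their ADA level in 22Rv1, so that this difference shrinks by construction. ATOH1 differed by 3.81 (SE 0.55, adjusted p 2.58e-05), a fitted value that depends on the prior count of that fit, MND1 by 2.16 (SE 0.26, adjusted p 6.38e-07), APOE by -3.18 (SE 0.59, adjusted p 5.13e-04) and DMKN, an epidermal secreted protein, by -4.44 (SE 1.13, adjusted p 0.0151). DMKN lost its call without C4-2B Ai_ND 1 (adjusted p 0.0530). EPS8L3 differed by 4.02 (SE 1.13, adjusted p 0.0302), and without the library labelled C4-2B Ai 2 by -0.57 (adjusted p 1.00), so that 1 library made this call. In C4-2B this contrast contains the distance between Ci and the other series. Without the 5 doubted libraries the count was 908.

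In ADA over expression vs Control 0 genes were called alike in both lines, since 22Rv1 had 0 calls. In Ai_ND against Ci the lines shared calls among 14214 genes tested in both. Of 208 genes lower in 22Rv1, 180 were lower in C4-2B, where independent lists would share 53.4 (Fisher's exact test p = 2.33e-77), and of 41 higher, 26 were higher in C4-2B, where 9.43 would be shared (p = 3.64e-08, two-sided, with genes treated as independent). APOE, lower in Ai_ND in both lines, and ELL2, CYP4F8 and LOX, higher in both, are among them. In 22Rv1 chance cannot be excluded for Ai_ND against Ci, since 9 of 100 splits, the real one included, gave as many calls. With the host-list covariate 0 genes were called in that line. In C4-2B the comparison called 7590 of 15712 genes. A difference between libraries that many genes share could also give this overlap, and that was not tested. The Fisher p-values therefore do not show that single genes respond alike. In Ai against Ai_ND the lines shared 0 calls, of 81 higher and 13 lower in 22Rv1 and 6 higher and 1 lower in C4-2B.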

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

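Of the tests in this part, those of the 3 libraries against their label, those of the C4-2B Ci series and those of host cells in the third pattern were chosen only after the result was seen.

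In 22Rv1, the ADA level of 3 libraries went against the label, and the library labelled Ci 5, at 64.9 CPM, stood far from the others of its group. RNA of C4-2B Ai tumours in that library would have brought at least 598 egfp counts, since every C4-2B Ai library carried egfp, and 0 were seen (95% bound 3.69, for counting error alone), which argues against this source. Low depth in the libraries labelled Ai 3 and Ai 6 is argued against as well, since 619 and 571 ADA counts were expected at the lowest level of the other Ai libraries, and 131 and 107 were seen (95% bounds 155 and 129, for counting error alone). An exchange of libraries between Ci and Ai cannot be told apart from tumours that gained or lost ADA, because 0 genes other than ADA were called in 22Rv1 Ai against Ci by edgeR (856 at an unadjusted p under 0.05, 1 by DESeq2) to mark the groups. A direct exchange with the library labelled Ci 5 could account for Ai 3 or for Ai 6, but not for both. A biological difference in induction between tumours was not tested.

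The C4-2B Ci series stood apart from Ai and Ai_ND. Poor RNA in the libraries labelled Ci 4 and Ci 5 is excluded as the whole cause, since 7320 genes were called in Ai_ND against Ci without them. With the host-list covariate 3655 genes were still called in Ai_ND against Ci. The median change of the 7590 genes went from 0.86 (median SE 0.20) to 0.91 (0.32). As a set these changes thus do not follow the marker mean. That mean may miss host reads of other kinds, so reads of host cells are not excluded. Another population of tumour cells in Ci stays open, since the chromosome Y genes had a median of -3.26 in Ai_ND against Ci, and the design confounds it with whatever the title code stands for. A biological effect of what sets the series apart was not tested.

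In both lines edgeR called genes between Ai_ND and each of Ai and Ci, though in 22Rv1 chance cannot be excluded for Ai_ND against Ci. A candidate explanation is an exposure shared by Ci and Ai and absent from Ai_ND, and its test could have failed. Any other difference that sets Ai_ND apart in both lines would pass it too, so a pass does not single out an exposure. In 22Rv1 the reporter tdtomato also set Ai_ND apart, at 7.11 to 9.86 CPM (n = 5). It stood at 0.642 to 1.65 CPM in Ci and 0.798 to 1.86 CPM in Ai (n = 6 each). Over the 100 C4-2B genes with the smallest p in Ai against Ai_ND, the called ones left out, the mean log2 difference in 22Rv1 along the C4-2B direction was 0.195 (mean log2) for Ai against Ai_ND (exact p = 0.00433, 74 genes with the same sign) and 0.299 for Ci against Ai_ND (exact p = 0.0152, 81 genes), with 462 arrangements each and the same Ai_ND libraries in both. In C4-2B 2 of 3 genes kept their call by edgeR with the host-list covariate (adjusted p 1.76e-05 for NUDT9 and 0.00857 for HSD17B11). RUFY3 lost it (0.103) with its change about as large, at 1.06 (SE 0.18) before and 1.03 (SE 0.19) after. The changes of these genes thus do not follow the marker mean, which may miss host reads of other kinds. NUDT9 and HSD17B11 are neighbours on chromosome 4, so they are not independent. On that chromosome 3 genes were called higher and 1 lower in C4-2B Ai against Ai_ND, and what places these calls together was not tested. In 22Rv1 host cells and an exposure cannot be told apart, since with the covariate edgeR called 0 genes in Ai against Ai_ND (2571 at an unadjusted p under 0.05, DESeq2 not run), while the median change of the 119 genes went from 0.88 (median SE 0.16) to 0.74 (0.22), and what was given to each series is not given in the sources used here.

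Besides ADA, 22 measures in 1 library each lay far from the rest of their group, 23 of 264 groups tested (8.7%), where chance gives about 1 in 20. In 22Rv1 these were tdtomato in Ai_ND 5 (7.11 CPM), APOE in Ai 6 (20.2 CPM), COL6A2 in Ai_ND 4 (18.7 CPM), MEIS3 in Ci 4 (27.2 CPM), ATOH1 in Ai_ND 4 (18.5 CPM) and FOS in Ci 1 (48.0 CPM). In the C4-2B Ci series they were APOE (12.3 CPM) and ATP1B2 (63.9 CPM) in Ci 6, FBXL2 in Ci 5 (1.93 CPM) and TJP1 in Ci 2 (421 CPM). In C4-2B Ai_ND 6 they were APOE (0.735 CPM), ACP3 (188 CPM), SRM (232 CPM) and TOP2A (122 CPM). In other C4-2B Ai_ND libraries they were QPRT in Ai_ND 4 (9.88 CPM), and RUFY3 (16.6 CPM) and ADRA2A (50.1 CPM) in Ai_ND 2. In C4-2B Ai they were CPNE4 in Ai 5 (12.6 CPM), FBXL2 (1.40 CPM) and ENSG00000286598 (8.30 CPM) in Ai 4, RPL3 in Ai 1 (3964 CPM) and PGR in Ai 3 (4.22 CPM).

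The effect of ADA over expression vs Control differed between lines for 949 genes by the interaction test. In C4-2B this contrast contains the distance between Ci and the other series, so the values below can hold that distance. Of the 1322 genes called in that line, 1261 were called in the same direction in Ai_ND against Ci and 6 in Ai against Ai_ND. EPS8L3 was at -0.57 without the library labelled C4-2B Ai 2, so that 1 library made its call. Named genes with a larger value in C4-2B, on the log2 scale, were EPS8L3 (4.02), ATOH1 (3.81), POC1B-GALNT4 (3.80), ADAM1A (3.64), ESR2 (3.02), SYCP2 (2.80), ADA (2.28), MND1 (2.16), ACP3 (2.04), SYCE2 (1.97), TRPM8 (1.97), RRM2 (1.86), NDC80 (1.82), TK1 (1.80), TYMS (1.80), KIF20A (1.73), CPNE4 (1.68), SYT4 (1.62), NUSAP1 (1.58) and DPP4 (1.56). Smaller differences of that sign were KIF23 (1.34), GNMT (1.14), KIF11 (1.07), CLDN3 (1.03), PNP (0.84), SLC45A3 (0.76), SRM (0.71), TJP1 (0.67), SHMT1 (0.60) and NT5C3A (0.46). Negative differences were DMKN (-4.44), LCN10 (-4.36), APOE (-3.18), LINC02568 (-2.97), SAGE1 (-2.73), QPRT (-2.19), LRP1 (-2.00), FNDC5 (-1.91), FBXL2 (-1.85), OPTN (-1.61), BST2 (-1.50), PROCR (-1.44) and COL6A2 (-1.02).

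Reporter identifiers, which no comparison used, gave counts in some groups. In 22Rv1, tdtomato stood at 9.17 ± 1.16 CPM in Ai_ND (SD, n = 5), against 1.04 ± 0.352 CPM in Ci (SD, n = 6) and 1.38 ± 0.449 CPM in Ai (SD, n = 6). In C4-2B, egfp had a mean of 730.8 CPM, and 1 count of it was seen in all 22Rv1 libraries together. By C4-2B series it stood at 860 ± 834 CPM in Ci, 841 ± 303 CPM in Ai_ND and 492 ± 274 CPM in Ai (SD, n = 6 each). The Ci libraries ran from 215 to 2340 CPM.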

How the results depend on the processing

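The setting without the 5 doubted libraries and its values were chosen only after the result was seen, and the remaining settings were planned. Where a count moved, the cause was not tested, except that a minimum change of 1 on the log2 scale lowers what can pass by construction. With that minimum change the counts were 46 (22Rv1 Ai against Ai_ND), 89 (22Rv1 Ai_ND against Ci), 358 (C4-2B ADA over expression vs Control), 2395 (C4-2B Ai against Ci), 3049 (C4-2B Ai_ND against Ci) and 435 (difference between lines). Without a filter on low counts they were 3 (22Rv1 ADA over expression vs Control), 851 (C4-2B ADA over expression vs Control) and 628 (difference). With DESeq2 they were 34, 354, 1 and 653 in 22Rv1 (ADA over expression vs Control, Ai against Ai_ND, Ai against Ci, Ai_ND against Ci) and 19 in C4-2B Ai against Ai_ND. The host-list covariate gave 0 in 22Rv1 Ai against Ai_ND and in Ai_ND against Ci, and 3655 in C4-2B Ai_ND against Ci. With only the groups compared, 22Rv1 Ai against Ai_ND gave 329 and Ai_ND against Ci 78. Pooling the Control series gave 3 in C4-2B. A block for the title set gave 2 in 22Rv1 ADA over expression vs Control. Without the doubted libraries the 22Rv1 counts were 1, 26, 1 and 434, and C4-2B ADA over expression vs Control gave 2402. In ADA over expression vs Control 0 lists passed by an estimated correlation in 22Rv1 and 1 in C4-2B, and by fry 0 and 6.

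A block for the replicate number gave 151 in 22Rv1 Ai_ND against Ci and 5 in C4-2B Ai against Ai_ND, and moved no other count by over 1.5 times. In 22Rv1 Ai_ND against Ci, TMEM45B, S100A14, PRAP1, COL1A1, ELL2 and LOX lost their calls with this block (adjusted p 0.0510 to 0.0819), and in 22Rv1 Ai against Ai_ND the block called ADA (0.0497). In C4-2B Ai against Ai_ND, SYNE2, RUFY3, GASK1B and ESR2 lost their calls with this block (adjusted p 0.235, 0.0876, 0.374 and 0.573). Samples of the same number were not paired, as their correlations ran from -0.619 to 0.446, with 14 of 34 over 0.1.

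Leaving out 1 library gave 0 to 2 genes in 22Rv1 ADA over expression vs Control, 55 to 187 in Ai against Ai_ND, 0 to 1 in Ai against Ci and 110 to 563 in Ai_ND against Ci. In C4-2B it gave 836 (without Ai 1) to 1599 (without Ai_ND 6) in ADA over expression vs Control and 5 to 9 in Ai against Ai_ND. The difference of EPS8L3 between lines ran from -0.57, the 1 value that reversed, without C4-2B Ai 2, to 4.75 without C4-2B Ci 6. Of named-gene results in all these fits, 1949 kept their side of the threshold, 88 lost a call, 5 gained 1 and 1 reversed. DESeq2's size factors in edgeR left 110 of 111 named-gene results on their side. At the depths here, the simulated recovery of 1.5-fold changes was 53% in 22Rv1 and 29.2% in C4-2B for ADA over expression vs Control. Smaller changes were not simulated. Differences between libraries that many genes share were not simulated either, so real recovery may be lower.

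Other splits of the libraries tested how often chance gives as many calls. With 100 splits the smallest share possible is 1 of 100, and the shares were not adjusted over the results tested. In 22Rv1 Ai against Ai_ND chance is unlikely (119 genes, highest other split 1, as many in 1 of 100), and likewise in C4-2B for Ai against Ai_ND (9, highest other 0, 1 of 100), Ai against Ci (6397, 2453, 1 of 100) and Ai_ND against Ci (7590, 4886, 1 of 100). Few splits reached the counts of C4-2B ADA over expression vs Control (1322, 4014, 3 of 100) and of the difference between lines (949, 478, 1 of 60). Those splits moved libraries among all 3 series, so the distance between Ci and Ai_ND can pass them without an effect of ADA. Of the 1322 genes, 1261 were called in the same direction in Ai_ND against Ci and 6 in Ai against Ai_ND. Chance cannot be excluded in 22Rv1 for Ai_ND against Ci (283, 3582, 9 of 100), nor for the list counts of ADA over expression vs Control in 22Rv1 (10, 19, 38 of 100) and C4-2B (11, 18, 32 of 100). For 22Rv1 ADA over expression vs Control and Ai against Ci the real count is 0, so that 100 of 100 splits give as many by construction and nothing is decided (highest others 1815 and 1135). What the splits that called several times the real count have in common was not tested.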

Other observations

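The tests of lists in this part were all planned. In C4-2B, of 18 de novo purine synthesis genes 16 rose and 1 fell in Ai_ND against Ci, over all genes and over the list alone, around a median of 0.91 (camera adjusted p 9.35e-06, and adjusted p = 0.482 with an estimated correlation). SHMT2, which supplies 1-carbon units in mitochondria, rose by 0.82 (SE 0.15, adjusted p 1.98e-04) and MTHFD2 by 1.38 (SE 0.15, adjusted p 9.60e-07). Of 20 glycolysis genes 14 rose and 0 fell, and 14 over the list alone (median 0.89, camera adjusted p 4.79e-04, adjusted p = 0.482 with an estimated correlation). ENO1, the glycolytic enolase, rose by 1.45 (SE 0.23, adjusted p 5.66e-05), from 464 ± 179 CPM in Ci (SD, n = 6) to 1268 ± 83.8 CPM in Ai_ND (SD, n = 6). Of 34 MYC and ribosome biogenesis genes 25 rose and 0 fell, and 25 over the list alone (median 0.71, camera adjusted p 4.46e-08, adjusted p = 0.0600 with an estimated correlation). SHMT2, MTHFD2 and ENO1 were chosen after their values were seen. The libraries labelled Ci 4 and Ci 5, with mitochondrial shares of 46.1% and 39.4%, belong to the Ci series.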
